A study of Homo sapiens with 17 samples.

How the data were processed

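Small RNA libraries were sequenced from HCT116 cells, a human colorectal carcinoma line, in which the DROSHA gene is disrupted. Per the labels' protocols, the cells were transfected with GFP or with wild-type or mutant DROSHA carrying a TEV site and an HA tag, and were harvested on day 3. Per the labels' protocols, 30 synthetic spike-in RNAs were added to 10 µg of RNA, fragments of 18 to 30 nt were gel-purified, and both adapters carried 4 random nucleotides. The tools named per the submitters' processing notes are cutadapt, Bowtie2, SAMtools and bedtools, with genome build hg38 and no versions.

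The deposited raw table holds 1 read count per miRNA hairpin and library, for 625 hairpins and 17 libraries. In the deposited normalized table each signal value equals the count plus 1, multiplied by 1 factor per library chosen by the authors, in 100% of entries within 0.1. The factor's origin is not stated in the notes or labels. It brought the summed value of the 20 hairpins of the DROSHA-independent list closer together between the 14 libraries of experimental Group 1. The coefficient of variation of that sum was 8.44% after the factor and 22.4% before it. miR-320a makes up most of the sum (94651 of 122555 counts in the Group 1 wild type), so this does not describe the single hairpins. How reads that match several hairpins were assigned is not stated per the submitters' processing notes, so values of multi-copy hairpins such as let-7a-1, miR-16-2 and miR-24-1 are uncertain. Removal of duplicate reads by the random nucleotides is not stated there either, and counting intervals cover counting error only.

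The labels give 2 experimental groups. Group 1 holds 14 libraries, with GFP, wild type, a deletion of the C-terminal double-stranded RNA-binding domain (114 residues), PhosMut (K1262A and Q1318A), the M mutants M1 to M5, ShortLinker1 and 2, and LongLinker1 to 3. Group 2 holds 3 libraries, with a second wild type, Q1266H and Q1267E/L1270S. Each library is a different construct except wild type, which has 1 library in each group. Tests between classes therefore use the spread between constructs of a class, and the lone wild-type library is assumed to vary like them.

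Class comparisons were fitted to counts with the quasi-likelihood F test of edgeR 4.0.16 (TMM factors, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. M against linker mutants was fitted on 10 libraries. The comparisons with wild type and LongLinker against ShortLinker came from 1 fit of 11 libraries in 4 classes. Lists of miRNA families and clusters, of DROSHA-independent hairpins and of miRNAs of other cell types or serum were tested with camera in limma 3.58.1 (voom, preset correlation 0.01, then an estimated correlation, adjusted over lists), where at least 3 members were measured. Lists named by their first member are the miR-183 cluster (with miR-96 and miR-182), the miR-130 list (with miR-301 and miR-454), the miR-148 list (with miR-152) and the miR-10 list (with miR-99, miR-100 and miR-125). The lists of miR-221 (with miR-222), miR-34, miR-192 (with miR-194 and miR-215) and miR-103 (with miR-107) had fewer tested members and give medians only. The level of DROSHA-made miRNAs was taken as the summed counts of all other hairpins per summed count of the DROSHA-independent list (24 names planned, 20 hairpins measured), with an exact two-sided permutation test on log2 values. Percentages of wild type were computed as count times deposited factor, relative to the wild type of the same group, with 0 counts set to a floor of 3 counts per library.

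Constructs with 1 library were not tested. Their ratios of CPM (counts scaled to library size, with 0.5 added to each count for log2 ratios), for hairpins with at least 100 counts in either library, were set beside the central 95% of the log2 ratio between the wild-type libraries. A hairpin is called higher or lower there when it lies outside that range and beyond 1 in size on the log2 scale.

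Named hairpins follow a rule set before the data were examined: up to 12 in each direction by fold among those passing the test with a mean of at least 100 CPM, up to 8 in each direction for single constructs, and any member of the lists. Alternatives were RLE factors, factors from the DROSHA-independent list, DESeq2 1.42.0, no count filter, limma on the deposited values with pseudocounts of 1 and 10, both wild-type libraries together, each library left out in turn, and the number in the construct name as a replicate block. The number's correlation of residuals was positive in all 7 same-number pairs (0.155 to 0.687, mean 0.412), but ran from −0.713 to 0.713 in pairs of different numbers (mean −0.105, highest for M5 with ShortLinker1), so the numbers are not shown to be batches; blocked values are given where they move a result, those of single hairpins planned beforehand and those of the lists added after the data were seen. The numbers are parts of construct names, and deviations in a class of 2 mirror each other by construction. Summing hairpin copies, leaving out the DROSHA-independent list, comparing the domain deletion with GFP, the DROSHA-independent factors without M5, the level of DROSHA-made miRNAs as a covariate, levels against the deposited scale or a single reference hairpin, and the Group 2 hairpins relative to the DROSHA-independent sum were added after the data were seen.

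The fits were tested on simulated data with 200 changed hairpins in 20 runs, raised and lowered in equal number. In the measured comparisons with wild type most called hairpins were lower, a setting that the simulation did not cover. Its rates need not hold for those comparisons. M against linker recovered 38.2%, 89.0% and 98.3% of changes of 2-, 4- and 8-fold, with 3.39% false calls. M against wild type recovered 7.27%, 44.1% and 72.0%, LongLinker against wild type 7.03%, 39.9% and 71.6%, ShortLinker against wild type 4.01%, 25.4% and 58.8%, and LongLinker against ShortLinker 12.4%, 60.4% and 84.9%. A list of 10 members moved 4-fold was called in 20 of 20 runs in each of 3 comparisons, and an unmoved list in 1 of 20 runs for M against linker and 0 in the other comparisons. Simulated hairpins were drawn independently, so members of a simulated list were not correlated. In the data the estimated correlation was high in several lists, such as 0.869 for DROSHA-independent hairpins in M against linker. The simulated list rates therefore need not hold for the measured lists.

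Hairpin positions are those of GENCODE release 29 on GRCh38, and hairpin folds were predicted with RNAfold 2.7.2. Arm ratios, scaling by spike-ins and the planned mismatched GHG list test were not run, since rows are whole hairpins, no spike-in rows are in the tables, and mature coordinates were not analysed here.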

Results

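Small RNAs were counted in DROSHA-null HCT116 cells after transfection with GFP or a DROSHA construct. DROSHA is the nuclear RNase III that releases most miRNA hairpins from their primary transcripts, and its double-stranded RNA-binding domain (dsRBD) lies at the C terminus. The constructs altered that domain or the linker before it. M1 to M4 replaced Q1266, Q1267 and further residues up to I1281, while M5 left Q1266 and Q1267 in place. The linker mutants replaced the linker residues DWN, with DG or G in ShortLinker1 and 2, and with DWNNNN, DWNNN or DWGGSN in LongLinker1 to 3. M4 is labelled with D1270S beside L1270H. Total counts ranged from 120544 to 921871 in the 14 Group 1 libraries and from 272209 to 558891 in the 3 Group 2 libraries. In Group 1 they were 129109 for GFP, 921871 for wild type, 139851 for the dsRBD deletion, and 252690 for PhosMut. M1 to M5 had 238673, 365554, 358651, 379622 and 120544 counts. ShortLinker1 and 2 had 205643 and 252198, and LongLinker1 to 3 had 274903, 511494 and 512568. In Group 2 wild type had 558891 counts, Q1266H 365844 and Q1267E/L1270S 272209. Intervals cover counting error only. Apart from the class tests, values are from 1 library each.

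The first question was how far each construct restored DROSHA-made miRNAs, measured against hairpins that form without DROSHA, such as miR-320a, miR-484 and miR-877. DROSHA-independent hairpins held 79.2% of counts in GFP (exact binomial 95% interval 78.9 to 79.4) and 13.3% in wild type (13.2 to 13.4). They held 80.2% in the dsRBD deletion (80.0 to 80.4) and 43.1% in PhosMut (42.9 to 43.3). Relative to them, all other hairpins stood at 4.04% of wild type in GFP and 3.79% in the dsRBD deletion. Both values include hairpins outside the list that were also kept in GFP. PhosMut reached 20.2% of wild type. M mutants averaged 35.7% ± 13.1 (SD, n = 5), from 17.1% in M5 to 47.6% in M4. ShortLinker constructs averaged 32.7% ± 6.82 (SD, n = 2) and LongLinker constructs 39.8% ± 9.26 (SD, n = 3). In Group 2, Q1266H stood at 34.8% and Q1267E/L1270S at 25.5% of their own wild type. The Q1266H value depends on the reference, since its summed DROSHA-independent hairpins were at 200.3% of wild type on the deposited scale. Its other hairpins were at 69.9% on that scale, 83.9% against miR-484 and 32.3% against miR-320a. The M and linker classes differed by −0.12 on the log2 scale, less than the spread within the classes (exact two-sided permutation p = 0.754, n = 5 and 5, smallest possible 0.00794). Without M5 the difference was 0.12 (exact permutation p = 0.651).

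**Figure D1:**
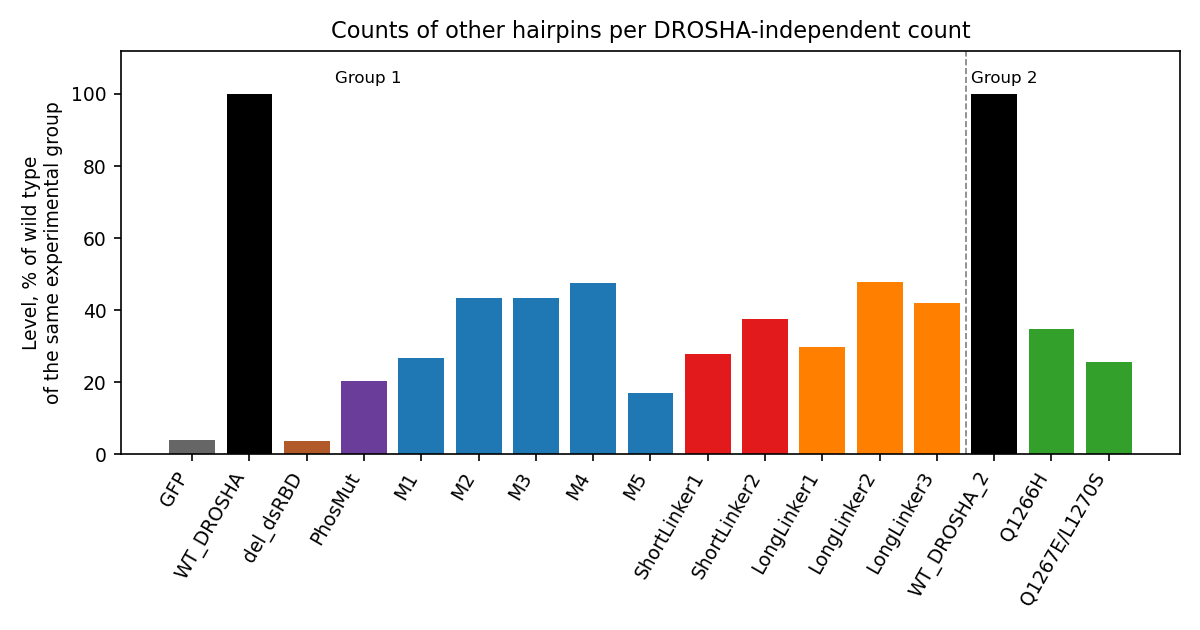
Counts of other hairpins per DROSHA-independent count in each of the 17 libraries, as percent of the wild type of the same experimental group, with 1 bar per library. GFP and the dsRBD deletion stand at 4.04% and 3.79%, and the M and linker mutants between 17.1% and 47.9%.

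GFP cells show which hairpins depended on DROSHA. let-7b, a member of the let-7 family of differentiation-linked miRNAs, had 0 counts in GFP and 4384 in wild type, at least 205-fold lower by CPM. miR-28, miR-30b, miR-33b and miR-200b also had 0 counts in GFP and were at least 136-fold, 117-fold, 117-fold and 88.3-fold lower. miR-99b had 1 count in GFP and 9363 in wild type, which is 1311-fold lower by CPM with a 95% counting interval from 235 to 51799. miR-25, of the miR-106b cluster, had 1 and 6339 counts, and miR-30d had 1 and 5897. By CPM, 160 of 197 hairpins were lower and 37 higher. The higher ones included miR-6803 (13.1-fold, interval 9.84 to 17.5), miR-6765 (11.1-fold), miR-1236 (10.8-fold), miR-6777 (10.7-fold), miR-1228 (10.2-fold), miR-6747, miR-3620 and miR-6726. On the deposited scale 0 hairpins were higher and 160 were lower. On that scale the 187 hairpins outside the DROSHA-independent list had a median of 0.317% of wild type, 72 of them had 0 counts, and 27 stayed above 50%. DROSHA-independent hairpins had a median of 118%.

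Deleting the dsRBD removed most of the DROSHA-dependent hairpins. miR-98, miR-505, miR-342, miR-181b-2, miR-328 and miR-590 had 0 counts in the deletion, with 1145, 784, 719, 617, 590 and 557 in wild type. miR-98 was therefore at least 57.9-fold lower by CPM and miR-590 at least 28.2-fold lower. let-7b had 3 counts against 4384 (95% counting interval 75.8-fold to 1075-fold lower), and miR-151a had 1 count against 1803. By CPM 158 of 195 hairpins were lower and 35 higher, among them miR-6803 (10.8-fold), miR-6786 (10.5-fold), miR-6765 (10.0-fold), miR-7111 (9.85-fold), miR-877 (8.48-fold), miR-1228 (8.48-fold), miR-1976 and miR-3064. On the deposited scale 0 were higher and 160 lower, and hairpins outside the DROSHA-independent list had a median of 0.473% of wild type.

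PhosMut, with K1262A and Q1318A, lost some hairpins and kept others. miR-130b had 0 counts against 985 in wild type (at least 90-fold lower by CPM), and miR-590 had 0 against 557 (at least 50.9-fold). miR-374a had 4 counts against 2835 (interval 75.8-fold to 714-fold lower). miR-340 had 1 count against 811, miR-181b-2 had 1 against 617, and miR-505 had 2 against 784. miR-7-1 and miR-1287 had 0 against 254 and 228. By CPM 96 hairpins were lower and 38 higher. The latter included miR-6786 (6.25-fold), miR-6803 (5.88-fold), miR-6765 (5.65-fold), miR-6858 (4.91-fold), miR-5088, miR-1237, miR-1976 and miR-6777. On the deposited scale 136 were lower and 0 higher. Of the 185 hairpins outside the DROSHA-independent list, 116 stood under 10% of wild type, 33 between 10% and 50%, and 36 above 50%. In GFP 27 of 187 such hairpins stood above 50%, so the 36 include hairpins kept without DROSHA, such as miR-6803 and miR-6765. The miR-183 cluster had a median of 86.4% of wild type in PhosMut, and the miR-15/16 family 3.92%. Members of the miR-15/16 family lay far apart, so its median does not describe each of them. The log2 count ratio of miR-503 to miR-424 was −7.09 in PhosMut and −0.94 in wild type.

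Against wild type, M mutants lost many hairpins almost completely and kept others. miR-15a, which with miR-16 targets BCL2, fell by 8.08 on the log2 scale (SE 0.88, edgeR adjusted p = 5.78e-05). miR-34a, a transcriptional target of p53, fell by 6.24 (SE 0.79, adjusted p = 0.000109), to 0.634% ± 0.198 of wild type (SD, n = 5). miR-221 fell by 5.45 (adjusted p = 0.00324), to 1.26% ± 1.44 of wild type (SD, n = 5). Its neighbour miR-222 stood at 89.4% ± 22.0 (SD, n = 5). miR-99b fell by 5.16 (adjusted p = 0.00271), to 1.52% ± 1.37 (SD, n = 5), beside miR-125a at 116% ± 28.8 (SD, n = 5). miR-503 fell by 5.50, to 1.06% ± 0.753 (SD, n = 5), beside miR-424 at 91.6% ± 18.6. miR-139, miR-151a, miR-590, miR-26b, miR-186, miR-505 and miR-107 fell by 6.80, 6.36, 5.85, 5.20, 5.14, 4.86 and 4.70. By edgeR, 154 of 431 hairpins changed, 30 higher and 124 lower, and 227 had an unadjusted p under 0.05.

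Fewer hairpins rose against wild type, and most of these calls depended on the scaling. They included miR-27a (1.44, SE 0.38, edgeR adjusted p = 0.0102), miR-125a (1.22, adjusted p = 0.0300), miR-6803 (1.70), miR-6786 (1.58), miR-5094 (1.51), miR-6893 (1.49), miR-7112 (1.45), miR-4723 (1.31) and miR-6743 (1.21). With factors from the DROSHA-independent list the median of all hairpins shifted by −0.94 and 1 hairpin was higher (miR-6869, outside the naming rule and chosen after its value was seen) against 140 lower. RLE factors shifted it by −0.74. On that DROSHA-independent scale miR-27a stood at 0.46 (adjusted p = 0.534) and miR-125a at 0.24 (adjusted p = 0.786). miR-27a was called higher with these factors without M5 (0.63, edgeR adjusted p = 0.0237) and with DESeq2 (0.67, adjusted p = 0.00978).

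By list, the DROSHA-independent hairpins rose as a group in M mutants relative to the other hairpins (14 of 14 positive, 1 called, 0 adjusted over the list alone, camera adjusted p = 0.00933, adjusted p = 0.850 with an estimated correlation). The miR-17-92 cluster and its paralogs, a set that includes MYC-induced miRNAs, fell as a group (6 of 11 lower, 8 adjusted over the list alone, camera adjusted p = 0.0369, adjusted p = 0.850 with an estimated correlation). Within let-7, 6 of 11 members fell (6 adjusted over the list alone), and the list had camera adjusted p = 0.119. All 3 miR-26 members fell (3 adjusted over the list alone, list adjusted p = 0.165). In the miR-181, miR-130, miR-30 and miR-15/16 lists 3 members each fell (of 6, 5, 6 and 8 tested, and 3 each adjusted over the list alone), with list adjusted p of 0.147, 0.176, 0.165 and 0.241. In the miR-200 list 2 of 5 fell, and in the miR-29 and miR-148 lists 1 of 4 and 1 of 3 (the same counts adjusted over the list alone; list adjusted p = 0.542, 0.543 and 0.543). In the miR-10 list 1 of 7 rose and 1 fell (1 and 1 adjusted over the list alone, list adjusted p = 0.724). In the miR-23/27/24 list 1 of 6 rose (1 adjusted over the list alone, list adjusted p = 0.724). None of the 3 miR-183 members and none of the 5 miRNAs typical of other cell types or serum passed (0 adjusted over the list alone, list adjusted p = 0.724 and 0.799). With the replicate block 296 hairpins changed (137 higher, 159 lower) and let-7 was called down (adjusted p = 0.0205, and without the block adjusted p = 0.850 with an estimated correlation). With both wild-type libraries 250 changed.

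These neighbours lie close together on 1 strand. On GRCh38, miR-221 lies at chromosome X 45746157 to 45746266 and miR-222 at 45747015 to 45747124, both in an intron of MIR222HG. miR-99b (chromosome 19, 51692612 to 51692681), let-7e and miR-125a (51693254 to 51693339) lie in an intron of SPACA6. miR-503 (chromosome X, 134546328 to 134546398) lies in an intron of MIR503HG, with miR-424 at 134546614 to 134546711. miR-34a (chromosome 1, 9151668 to 9151777) lies in an exon of MIR34AHG and miR-15a (chromosome 13, 50049119 to 50049201) in an exon of DLEU2.

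LongLinker constructs also lost many of the measured hairpins against wild type. miR-34a fell by 6.07 on the log2 scale (SE 0.95, edgeR adjusted p = 0.00134) and miR-29c by 5.99 (SE 0.68, adjusted p = 0.000282). miR-15a fell by 5.41, miR-151a by 4.53, miR-584 by 4.27, miR-615 by 4.15 and miR-744 by 4.14. miR-505, miR-3200, miR-139, miR-340 and miR-19a, the last a member of miR-17-92, fell by 4.03, 3.88, 3.62, 3.58 and 3.57. The 4 higher hairpins were miR-27a (1.31, adjusted p = 0.0279), miR-125a (1.28, adjusted p = 0.0402), miR-6746 (1.52) and miR-6869 (1.79), of which the last pair lies outside the naming rule and was chosen after its values were seen. Members of 1 class differed widely: miR-26b had 4, 1533 and 263 counts in LongLinker1, 2 and 3, let-7i 63, 5382 and 1272, and miR-221 117, 7073 and 1759. By edgeR 96 of 431 hairpins changed, 4 higher and 92 lower, with 146 at an unadjusted p under 0.05. The replicate block gave 255 (97 higher, 158 lower), both wild-type libraries 154, the fit without LongLinker3 55, and DROSHA-independent factors 0 higher. With those factors miR-744, miR-139 and miR-19a stood at −4.74, −4.22 and −4.24, with adjusted p of 0.0620, 0.105 and 0.0682.

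ShortLinker constructs left the p53-linked miR-34a at 10 counts over both libraries, against 12217 in wild type (log2 change −9.44, SE 1.30, edgeR adjusted p = 0.00105). miR-26b had 8 counts against 4093 (−8.16, adjusted p = 0.0301), miR-139 had 6 against 1940 (−7.51, adjusted p = 0.00586) and miR-15a had 9 against 1981 (−6.99, adjusted p = 0.00298). miR-29c had 1 count against 1001. miR-221 fell by 7.06 (adjusted p = 0.0108), while miR-222 rose by 1.20 relative to the other hairpins (adjusted p = 0.0393) and stood at 100% ± 2.58 of wild type on the deposited scale (SD, n = 2). miR-151a, miR-590, miR-99b, miR-340, miR-584 and miR-744 fell by 6.25, 5.53, 5.46, 5.26, 5.22 and 5.17. miR-27a (1.88, adjusted p = 0.00586), miR-6803 (1.82), miR-7112 (1.68), miR-125a (1.63), miR-6743 (1.40) and miR-6799 (1.38) rose on the main scale. By edgeR 153 of 431 hairpins changed, 26 higher and 127 lower, with 212 at an unadjusted p under 0.05. The replicate block gave 320, both wild-type libraries 233, the fit without ShortLinker1 45 and that without LongLinker3 92. DROSHA-independent factors left 1 higher hairpin (miR-6854, outside the naming rule and chosen after its value was seen), with miR-222 at 0.12 (adjusted p = 0.886) and miR-26b at −9.22 (adjusted p = 0.0549). The 3 comparisons with wild type in Group 1 share the same wild-type library.

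M and linker mutants held different miRNAs. miR-29a, which targets collagen and DNMT3 mRNAs, had 25579 ± 10637 CPM in M mutants and 4751 ± 1955 in linker mutants (SD, n = 5 each), a log2 difference of 2.34 (SE 0.41, edgeR adjusted p = 0.00317). miR-200a, which represses ZEB1 and ZEB2, had 6773 ± 3082 and 991 ± 459 CPM (2.67, SE 0.46, adjusted p = 0.00317), and stood at 63.9% ± 35.9 of wild type in M mutants and 9.53% ± 5.94 in linker mutants (SD, n = 5 each). Its cluster neighbour miR-200b was higher by 2.43 (adjusted p = 0.0194). In the other direction, miR-30d had 754 ± 444 CPM in M mutants and 4439 ± 1801 in linker mutants (−2.65, SE 0.52, adjusted p = 0.00509). It stood at 5.41% ± 3.42 and 32.8% ± 19.0 of wild type (SD, n = 5 each). miR-301b had 62.8 ± 30.8 and 508 ± 388 CPM (−3.05, SE 0.60, adjusted p = 0.00509).

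Further hairpins higher in M mutants were miR-24-1 (4.31, SE 0.73), miR-1908 (3.63), miR-16-2 (3.36), miR-3200 (2.70), miR-455 (2.65), miR-339 (2.46), miR-197 (2.08), miR-149 (1.97) and miR-425 (1.88). miR-24-1 and miR-16-2 have copies elsewhere with the same mature sequence. Those copies moved differently, with miR-24-2 at 0.87 and miR-16-1 at −1.61. Since the assignment of shared reads is not stated, a rise of the mature miR-24 or miR-16 is not shown. Hairpins lower in M mutants were miR-98 of the let-7 family (−3.02), miR-30a (−2.42), miR-107 (−2.37), miR-224 (−2.14), miR-28 (−2.11), miR-574 (−2.08), miR-652 (−2.08), the epithelial miR-203a (−1.92, SE 0.36), miR-324 (−1.83) and miR-335 (−1.79). miR-203a had 411 ± 122 and 1433 ± 474 CPM and miR-324 had 1559 ± 960 and 5202 ± 2240 (SD, n = 5 each). On GRCh38, miR-29a lies at chromosome 7 130876747 to 130876810, miR-200a at chromosome 1 1167863 to 1167952 (intergenic), miR-30d at chromosome 8 134804876 to 134804945 (intergenic) and miR-301b at chromosome 22 21652981 to 21653058.

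**Figure D2:**
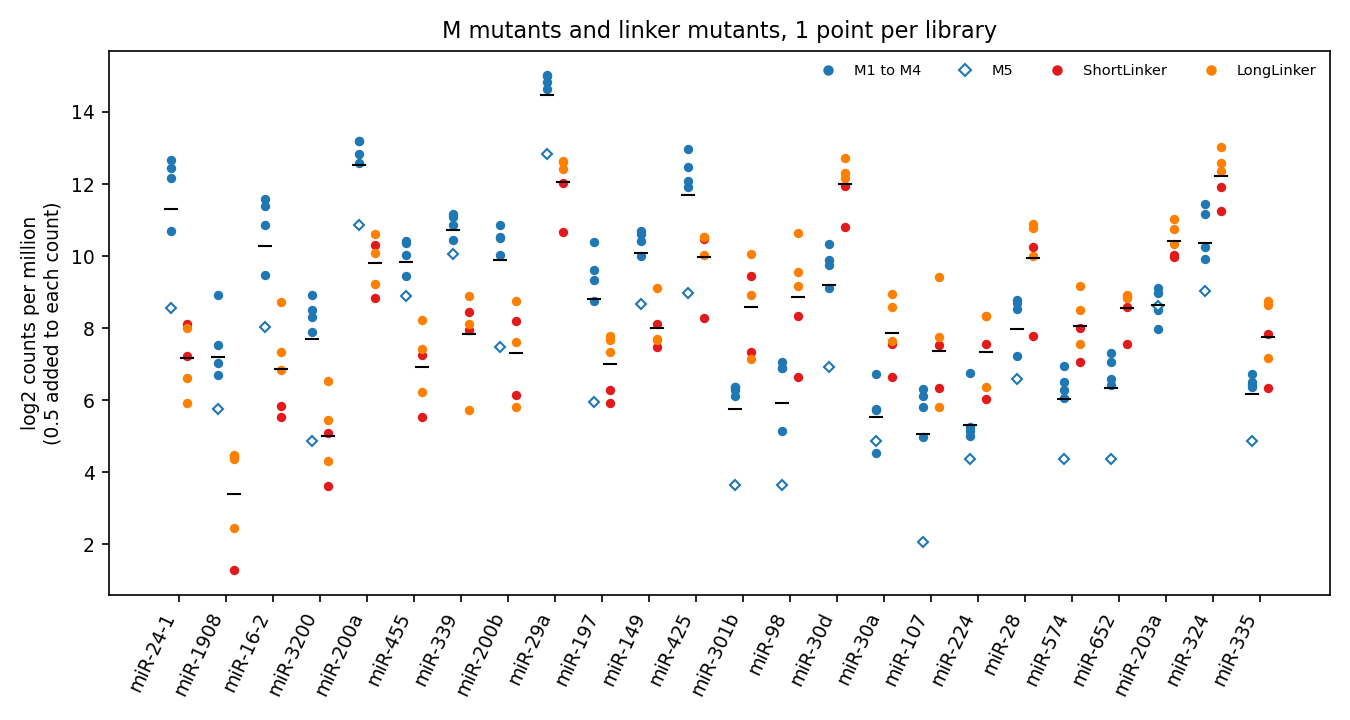
Log2 CPM (0.5 added to each count) of the 24 named hairpins in 5 M mutants and 5 linker mutants, 1 point per library, with black bars at class means and M5 as open diamonds. miR-29a averages 25579 CPM in M mutants and 4751 in linker mutants, and miR-30d 754 and 4439.

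By edgeR 47 of 294 hairpins differed between M and linker mutants, 17 higher and 30 lower, with 70 at an unadjusted p under 0.05. DESeq2 gave 56. In 25 hairpins (8.50%) the classes did not overlap, against 0.794% by chance, and 23 of these were among the changed ones. RLE factors gave 29 (13 higher, 16 lower), factors from the DROSHA-independent list 4 (without M5 24, with 20 higher and 4 lower, the reverse balance), limma on the deposited values 3, and the fit without M3 27 and that without LongLinker3 30. Under DROSHA-independent factors miR-24-1 (4.45) and miR-1247 were higher and miR-503 and miR-551a lower, of which miR-1247 and miR-551a lie outside the naming rule and were chosen after their values were seen. There miR-29a was at 2.43, miR-200a at 2.78 and miR-203a at −1.83 (adjusted p = 0.0646 each).

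Among the lists, the miR-29 family rose as a group in M against linker mutants (3 of 3 positive, 1 higher, 2 adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.522 with an estimated correlation; blocked adjusted p = 0.0292; adjusted p = 0.0550 with RLE factors). The 3 miR-29 hairpins tested were miR-29a (2.34), miR-29b-1 (0.69) and miR-29b-2 (1.53), and miR-29c was not among them. The miR-29b hairpins are copies whose read assignment is not stated, so the 3 are not independent members. In the miR-30 list 3 of 5 members were lower (3 adjusted over the list alone), and the list had adjusted p = 0.118. In the miR-183 cluster 1 of 3 was lower (2 adjusted over the list alone, adjusted p = 0.118). In the miR-200 list 2 of 5 were higher (2 adjusted over the list alone), with a median of −0.77, a mean of 0.55 and adjusted p = 0.462. In the miR-130 list 2 of 4 were lower (2 adjusted over the list alone, adjusted p = 0.443), and in let-7 2 of 9 were lower (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.773). The miR-15/16 list had 1 of 7 higher and 1 lower (1 and 2 adjusted over the list alone, adjusted p = 0.554), and the miR-23/27/24 list 1 of 6 higher and 1 lower (1 and 1 adjusted over the list alone, adjusted p = 0.654). In the miR-23/27/24 list the median was −0.35 and the mean 0.45. The miR-181 list had 1 of 3 lower (1 adjusted over the list alone, adjusted p = 0.863), with a median of 0.16 and a mean of −0.11. The miR-148 list had 0 of 3 (1 lower adjusted over the list alone, adjusted p = 0.571), and miRNAs of other cell types or serum 1 of 3 lower (1 adjusted over the list alone, adjusted p = 0.462). No member passed among 12 DROSHA-independent hairpins, 7 of miR-17-92 and its paralogs and 7 of miR-10 (0 adjusted over the list alone, adjusted p = 0.717, 0.605 and 0.571).

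LongLinker and ShortLinker constructs were compared to see whether linker length altered the profile. The let-7 family was higher as a group in LongLinker constructs (11 of 11 positive, 0 called, 0 adjusted over the list alone, camera adjusted p = 0.0278, adjusted p = 0.695 with an estimated correlation; blocked adjusted p = 0.00735; adjusted p = 0.0731 with RLE factors), with a median log2 difference of 1.35. Single libraries overlapped: the summed family stood at 3.35%, 24.1% and 10.8% of wild type in LongLinker1, LongLinker2 and LongLinker3, and at 1.92% and 5.11% in ShortLinker1 and ShortLinker2. let-7i stood at 6.32% ± 8.02 of wild type in LongLinker (SD, n = 3) and 1.80% ± 0.755 in ShortLinker constructs (SD, n = 2). By edgeR 0 of 431 hairpins changed (29 at an unadjusted p under 0.05, DESeq2 0), and the replicate block gave 9 higher. The miR-15/16, miR-30, miR-29 and miR-130 lists had median differences of 1.65, 1.16, 1.39 and 0.97 with adjusted p of 0.0599, 0.0889, 0.0889 and 0.0889. DROSHA-independent hairpins had 13 of 14 negative (adjusted p = 0.0610). With the block the miR-15/16, miR-30 and DROSHA-independent lists were called (0.0143 each, up, up and down), and without it each had adjusted p = 0.695 with an estimated correlation. The miR-17-92, miR-200 and miR-26 lists had adjusted p of 0.199, 0.210 and 0.250. The miR-183, miR-181, miR-23/27/24, miR-10 and miR-148 lists and that of other cell types or serum had 0.405, 0.723, 0.788, 0.889, 0.889 and 0.788. Adjusted over the list alone, 1 miR-181 and 1 miR-130 member were higher and 0 in the other lists. In the lists too small to test, M mutants had medians over members of 28.7% to 60.5% of wild type for the miR-221 cluster, 6.39% to 51.3% for the miR-103 list, 2.36% to 6.13% for the miR-192 list and 0.294% to 0.755% for miR-34. In the miR-221 and miR-103 lists the members lay far apart, so the median describes neither. miR-221 and miR-107 were strongly lower in M mutants, while miR-222 was kept. miR-103a-2 had a log2 change of 0.16 from wild type on the main scale, relative to the other hairpins. It was not kept in every M mutant, since the lowest list median of 6.39% leaves both members far below wild type there.

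In Group 2, a single substitution at Q1266 and a substitution pair at Q1267 and L1270 were set against the second wild type. In Q1266H, miR-374a had 8 counts against 452 (37.0-fold lower by CPM, interval 18.6 to 86.2), miR-130b had 9 against 432 (31.4-fold) and miR-1296 had 20 against 735 (24.1-fold). miR-505, miR-141, miR-148b, miR-151a and miR-139 were 15.5-fold, 15.6-fold, 13.5-fold, 13.1-fold and 12.4-fold lower. The 4 higher hairpins were miR-1224 (3.40-fold), miR-1237, miR-1228 and miR-320a (2.45-fold), and 22 of 154 were lower. None of these 4 would be called with the wild-type range turned round. On the deposited scale 1 was higher (miR-1224) and 26 were lower. On that scale miR-320a stood at 216% of wild type and the DROSHA-independent hairpins at a median of 191%. Other hairpins had a median of 51.1% there.

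Q1267E/L1270S lost more. miR-181b-2 had 0 counts against 338 (at least 54.9-fold lower by CPM), miR-1301 had 2 against 469, miR-503 had 1 against 164 and miR-501 had 1 against 157. miR-15a had 8 against 902 (54.9-fold lower, interval 27.8 to 128), miR-151a had 12 against 1281 (52.0-fold), miR-139 had 7 against 683 (47.5-fold) and miR-589 had 1 against 128. The higher hairpins included miR-1228 (4.16-fold), miR-424 (3.91-fold), miR-1224 (3.60-fold), miR-1227 (3.59-fold), miR-29b-1 (3.47-fold), miR-1237, miR-7111 and miR-3605. None of the higher hairpins would be called with the wild-type range turned round, as the largest log2 ratio was 2.06 (miR-1228). miR-424 and miR-29b-1 were low in the Group 2 wild type itself, with 102 and 68 counts against 972 and 521 in that of Group 1. By CPM 48 of 156 hairpins were lower and 18 higher, and on the deposited scale 75 and 0. Of 147 hairpins outside the DROSHA-independent list 55 stood under 10% of wild type on that scale, against 11 of 146 in Q1266H, and their median was 17.9%. Relative to the summed DROSHA-independent hairpins the counts were 63 and 30, and the gap narrowed to medians of 14.4% and 25.5%. The difference between the constructs was not tested.

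The wild-type libraries of the 2 experimental groups give the only spread for a single construct. Over hairpins with at least 100 counts, the SD of their log2 CPM ratio (Group 2 over Group 1) was 0.92, with a central 95% from −2.40 to 1.25, and 68.6% lay within 2-fold. miR-98 had 1145 counts in Group 1 and 96 in Group 2, miR-26b had 4093 and 417, and miR-424 had 972 and 102. This spread also holds any difference between the groups.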

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

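The tests of chance, of a common shift, of the level as a covariate and of M5 below were chosen after the result was seen, as was the deciding set of the motif test; the predictions for the covariate and the motif were written before their values. In M mutants, 45 measures (named hairpins and the level of DROSHA-made miRNAs) were searched for 1 library far from the other 4 (Dixon ratio of gap to range), which chance gives in about 1 in 20 groups, and 11 met it. M5, the library with the lowest count, was apart in 10 of them. It was lower in miR-301b (ratio 0.913, log2 CPM 3.64 against 6.13 to 6.36), miR-29a (0.832, 12.84 against 14.65 to 15.01), miR-335 (0.815, 4.86 against 6.37 to 6.72), miR-200b (0.757, 7.48 against 10.04 to 10.86) and miR-3200 (0.746, 4.86 against 7.88 to 8.91). It was also lower in miR-151a (0.746, 3.64 against 4.77 to 5.15), miR-425 (0.739, 8.97 against 11.93 to 12.98), miR-200a (0.734, 10.86 against 12.57 to 13.19) and miR-125a (0.721, 14.56 against 14.79 to 14.87). It was higher in miR-6803 (0.760, 8.71 against 8.07 to 8.23). In M5 miR-301b stood at 8.30 CPM, and miR-335 and miR-3200 at 24.9. These values and that of miR-151a rest on very few counts, so counting error is large there. miR-6803 was also kept in GFP, and DROSHA-independent hairpins held a larger share of counts in M5 (47.2%) than in the other M mutants. Its higher CPM in M5 therefore need not be a higher level. M2 was higher in miR-26b (0.801, 9.11 against 4.37 to 5.31).

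M and linker mutants differed in 47 hairpins. Of 100 splits of the 10 libraries into 5 and 5, 1 gave as many, the real one, and the highest other gave 16. Chance is thus argued against for the count, but not excluded. Only 100 of 126 possible splits were drawn. The other splits mix M and linker libraries, so a real class difference can lower their counts. The real split parts 5 of 7 same-number pairs; the highest count among the 41 other splits that part as many is 9, and among the 58 that part fewer it is 16. M5 alone is not the source, since 51 hairpins differ without it. A shift common to all DROSHA-made miRNAs is argued against by neighbouring hairpins under 10% of wild type in GFP. Their ratio needs no scaling and differed between the classes in 9 of 29 pairs (exact permutation, adjusted p = 0.0256 each). The pairs with let-7a-2, miR-16-2 and miR-24-1 among these hold a multi-copy hairpin of uncertain value, and miR-93 is in more than 1 pair. A pair kept in GFP, miR-1227 and miR-6789, also differed, so such ratios can differ without a difference in DROSHA processing. Another explanation is a difference in overall restoration to which each hairpin responds in its own way. The fit with the level as a covariate calls 67, all 47 among them, but cannot decide on it. The classes differed in level by only −0.12 (exact permutation p = 0.754), so the covariate could hardly take up a class difference.

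A mismatched GHG motif, which DROSHA's dsRBD is known to read, may set which hairpins M mutants hold. Among 133 hairpins under 10% of wild type in GFP, the difference in median log2 change between 24 with the motif and the rest was −0.027 (bootstrap interval −0.83 to 1.17; permutation p = 0.930), too wide to decide. Over all 294 hairpins it was −0.28 (31 with the motif, permutation p = 0.0399), which meets the prediction, but that set mixes DROSHA-made and other hairpins. The smaller set was taken as the deciding one, after these values were seen, because DROSHA-dependent hairpins carry the motif more often. With GHG alone, whatever the pairing, it was −0.03 (151 of 294, permutation p = 0.745). The motif was read from the outer 30 nt of predicted folds, an approximation, so the GHG explanation stays open.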

How the results depend on the processing

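The DROSHA-independent factors without M5, the level as a covariate, the list tests with the block, summed copies, the level without miR-320a and the Group 2 levels with other references were chosen after seeing the data. The cause was not tested where a count moved, unless stated. M against linker (47) became 29 with RLE factors (13 higher, 16 lower), 4 with DROSHA-independent factors, 24 with these without M5 (20 higher, 4 lower), and 3 and 2 with limma on deposited values at pseudocounts 1 and 10. Leaving out a library gave 27 to 51 (27 without M3, 30 without LongLinker3). The replicate block gave 56, the level as a covariate 67, copies summed 35 and no DROSHA-independent list 48. M against wild type (154) became 296 with the block and 250 with both wild-type libraries, 128 to 174 with a library left out and 136 without the DROSHA-independent list. LongLinker against wild type (96) became 255 and 154, with 55 to 118 (55 without LongLinker3). ShortLinker against wild type (153) became 320 and 233, with 45 to 206 (45 without ShortLinker1, 92 without LongLinker3). LongLinker against ShortLinker (0) became 9 with the block and 0 to 1 with a library left out (1 without LongLinker1). For the list tests, an estimated correlation gave 0 calls in M against linker, M against wild type and LongLinker against ShortLinker, RLE factors gave 0 in M against linker and in LongLinker against ShortLinker, and the block gave 4 in LongLinker against ShortLinker.

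The level difference of −0.12 kept its sign with the other references and on deposited values, and leaving out a library gave −0.25 to 0.12, turning without M5 (0.12). On deposited values and against miR-320a, miR-484 and miR-877, Q1266H (34.8%) stood at 69.9%, 32.3%, 83.9% and 41.3% of wild type, and Q1267E/L1270S (25.5%) at 31.7%, 25.5%, 26.9% and 24.4%; in Group 1 no library moved by over 1.41-fold with these references. For single constructs, the deposited scale gave 0 higher in GFP, 0 in the dsRBD deletion, 0 in PhosMut, 1 in Q1266H and 0 in Q1267E/L1270S, with 75 lower in the last. TMM factors gave 23 higher in GFP. No named hairpin turned its direction under any alternative in which single hairpins were checked. With copies summed they were not checked. Of 24 named for M against linker, 8 lost the call with RLE factors, 23 with DROSHA-independent factors, 24 on deposited values and 3 without a filter. Of 21 for M against wild type, 8 lost it with DESeq2 and 9 with RLE or DROSHA-independent factors. Of 14 for LongLinker and 19 for ShortLinker, 5 and 8 lost it with DROSHA-independent factors. With limma on deposited values at a pseudocount of 1, 10 of the 21 for M lost it, 8 of the 14 for LongLinker and 7 of the 19 for ShortLinker.

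These factors move all hairpins of a library with its DROSHA-independent sum, and shift the median of all hairpins by 0.11 in M against linker (RLE 0.12), −0.72 and −1.03 in LongLinker and ShortLinker against wild type (RLE −0.57 and −0.70), and 0.33 in LongLinker against ShortLinker (RLE 0.13). Not run: scaling by spike-ins, both arm-ratio tests and the planned mismatched GHG list test; the list without tRNA- and snoRNA-derived members changed nothing, as none is in the tables. GFP, the dsRBD deletion and M5, with 129109, 139851 and 120544 counts, limit what can be seen of rare hairpins.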

Other observations

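The test of transcription below was chosen after the result was seen, and those of shared reads and low counts before it. The dsRBD deletion and GFP libraries were also compared, after the data were seen. In the deletion 7 of 46 hairpins were higher and 0 lower than in GFP: miR-27a with 651 counts against 29 (20.7-fold by CPM, interval 14.3 to 31.2), miR-10a with 213 against 10, miR-29a with 162 against 21, miR-31 with 183 against 30, let-7i with 117 against 25, miR-21, a common oncogenic miRNA, with 639 against 147, and miR-221 with 122 against 30. Each construct has 1 library, so this is a value with no test.

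Hairpins less than 10 kb apart changed by different amounts from wild type to M mutants, and processing that differs between hairpins of 1 transcript is a hypothesis that could account for it. Over 43 neighbouring pairs the median absolute difference in log2 change was 1.86 (bootstrap interval 1.21 to 2.64), with 20 pairs over 2, so a common change in transcription, which would leave neighbours alike, is argued against; random pairs gave 2.28 (central range 1.52 to 3.16), and the ratios of neighbours differed between the wild-type libraries by a median of 0.53. Low counts as the whole source are argued against by 15 pairs with 1000 or more counts in wild type, whose median was 1.30 (0.71 to 2.79). Reads shared with near-identical copies cannot be told apart from it, since 15 pairs without a same-number relative gave 0.89 (0.71 to 3.48), below the bound of 1 set beforehand and above 0.5. Hairpin stability and different cleavage of host transcripts were not tested.

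The ratio of neighbours needs no scaling between libraries. In 11 of 43 pairs it differed between M and linker mutants (exact permutation p = 0.00794 each, the smallest possible, Benjamini-Hochberg adjusted p = 0.0310, n = 5 and 5). These pairs include miR-1227 and miR-6789, which were both kept in GFP cells, and miR-1227 is on the DROSHA-independent list. Their log2 ratio was −0.21 ± 0.28 in M mutants and 0.46 ± 0.23 in linker mutants (SD, n = 5 each). A ratio that differs is thus not by itself evidence of a difference in DROSHA processing. Among the 29 pairs of DROSHA-dependent hairpins, 9 differed (exact permutation, adjusted p = 0.0256 each). Those with let-7a-2, miR-16-2 and miR-24-1 hold a multi-copy hairpin of uncertain value. For miR-200a over miR-429 the log2 ratio was 5.69 ± 0.48 in M mutants and 2.09 ± 0.43 in linker mutants (SD, n = 5 each), with 2.29 in the Group 1 wild type and 3.43 in that of Group 2.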
